A study of Mus musculus with 20 samples.

How the data were processed

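The study measured RNA by sequencing in skin and skeletal muscle of the left hindlimb of C57BL/6J mice, collected 70 days after the limb was sham treated or received 35 Gy of electrons from a linear accelerator. The dose was given at ultra-high dose rate (FLASH) or at conventional dose rate (CONV), per the labels. Each tissue had 3 sham, 4 FLASH and 3 CONV libraries, 20 in total. All skin libraries belonged to batch 1 and all muscle libraries to batch 2, so batch and tissue cannot be told apart. The labels number the replicates of each group but do not state that each number is a separate animal, so p-values measure the spread between these samples, which may be partly technical. Libraries were made with a stranded total RNA kit after removal of ribosomal RNA, per the labels.

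The deposited files held, for each of 116116 mouse transcripts, an estimated count and a TPM value, which corrects for transcript length and library size, computed by the authors with kallisto, listed as version 0.5.0 with the mouse genome mm10, per the submitters' processing notes. The transcript annotation release was not given in the sources used here. Each file was 1 library, with no pooling. The deposited estimated counts were not normalized.

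Transcripts were assigned to genes by their identifier without its version in GENCODE M21, which uses the mouse assembly GRCm38 (mm10). This matched 98.5% of transcripts (114322), and 99.1% of the matched ones had the same length in both sources. The version number was 1 above that of M21 for 98.7% of the matched transcripts, so the authors' annotation was another release. Unmatched transcripts held 0.873% to 1.85% of the counts of a library and were left out. Estimated counts were summed over the transcripts of each of 35579 genes and rounded to whole numbers. Coordinates are those of GENCODE M21, counted from 1. kallisto divides reads between transcripts that share sequence, so values of near-identical copies and pseudogenes are uncertain.

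The library totals were 24396463 to 33250762 estimated counts in skin and 10198699 to 12336479 in muscle. In muscle the 10 most abundant genes took 60.0% to 65.1% of the counts, which left less depth for the rest. Intervals and floors given for low counts cover counting error only. Every pair of libraries within a group was compared by a chi-square test of counts over genes. The statistic was 8.46 to 429 per degree of freedom, so no pair agreed within sampling noise and all libraries were kept.

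Groups followed the GEO record under which each file was deposited. In 7 records (2 skin and 5 muscle) the file carried the library name that the labels give to another record. In skin, sham replicate 3 held a file named as a FLASH library and FLASH replicate 1 a file named as a sham library. In muscle, the files of sham replicates 2 and 3 were named as FLASH libraries, those of FLASH replicates 2 and 3 as sham libraries, and that of FLASH replicate 1 as another FLASH library. No CONV file was affected. Every comparison was therefore repeated with files assigned by library name and again without the disagreeing libraries. A further comparison set the 3 CONV libraries of each tissue against the other 7, which is the same under both assignments.

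The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust dispersion estimates, TMM normalization and the filterByExpr filter by group, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 3 groups of a tissue were fitted together so that they shared 1 estimate of the spread. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. Differences between tissues in a response were tested as an interaction over all 20 libraries, treated as independent. Library names carry the same numbers in both tissues, but the labels do not state that 1 animal gave both. Group levels are CPM with TMM scaling, as mean ± SD over libraries. Levels given with the tests between tissues, and CPM ratios of low counts, are without TMM scaling.

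A total of 35 gene lists with 543 entries, covering radiation response, inflammation, matrix, cell types of skin and muscle, and metabolism, were written from general knowledge. Lists with at least 3 tested members were analysed, which gave 34 lists in skin and 29 in muscle. Each list was tested with limma's camera (limma 3.58.1), which compares its genes with all others, with a preset correlation between genes of 0.01 and again with an estimated correlation. fry tested whether its genes moved one way on balance. Adjustment was over the lists of a comparison. Members were counted past the threshold over all genes tested and adjusted over the list alone. List scores per library are the mean log2 CPM of its members, with a prior count of 2.

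Genes were named by a rule. It took up to 8 higher and 8 lower protein-coding genes with the largest change among those with an adjusted p under the threshold, an average log2 CPM of at least 1 and no overlap between the libraries of the 2 groups. Where fewer than 4 genes passed, it took the 5 with the smallest p. It added up to 4 members of a described list with the smallest p, and always Cdkn1a, Col1a1, Col3a1, Krt14 and Adipoq in skin, and Cdkn1a, Col1a1, Col3a1, Myh4 and Myh7 in muscle. Groups, tests, lists, this rule and the planned variations of the processing were fixed before the data were examined.

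The planned variations were DESeq2 size factors in place of TMM, no low-count filter, the DESeq2 Wald test (1.42.0), the replicate number as a block, counts rebuilt from TPM and transcript length, only the compared groups in the fit, mitochondrially encoded genes left out, both treatments of the disagreeing files, and each replicate left out in turn. Added after the data were seen were the removal of 2 skin libraries rich in muscle RNA, list scores of fast muscle, hair shaft or slow muscle genes as covariates, list medians without each replicate, and splits of the libraries into other groups.

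The tests were checked on simulated counts with the means, library sizes and spread of the real data, in which 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn only from those with an average log2 CPM above 1. For the difference between tissues they were drawn from genes above 2 CPM in both tissues. The shares recovered therefore do not cover genes of lower expression. In skin, 11% of 2-fold and 70% of 4-fold changes were recovered for FLASH against sham, 5% and 51% for CONV against sham, 6% and 72% for FLASH against CONV, and 19% and 76% for CONV against all others. In muscle the shares were 75% and 95%, 73% and 98%, 79% and 99%, and 86% and 99%, in the same order. For the CONV difference between tissues they were 2% and 51%. With no change simulated, 0 genes were called in either tissue for CONV against sham. Where changes were simulated, 3 to 17 unchanged genes per comparison were also called. Each gene was drawn independently, so the simulations hold no structure that genes of a library share. Among 83 groups of library measures screened for a library far from the rest, only groups of 4 could be tested, so sham and CONV groups were not screened.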

Results

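The data were 20 RNA sequencing libraries from mouse hindlimb, 10 of skin and 10 of skeletal muscle, taken 70 days after sham treatment (3 libraries per tissue) or 35 Gy of electrons at ultra-high dose rate (FLASH, 4 libraries) or conventional dose rate (CONV, 3 libraries). FLASH delivers the whole dose within a fraction of a second, and the design asked how late responses of the tissues differed between the modalities. In skin, the libraries held 30624215, 33250762 and 29327697 estimated counts in sham, in order of replicate. They held 28598976, 29890496, 29499473 and 31985338 in FLASH and 26198366, 24396463 and 32448808 in CONV. In muscle they held 11973061, 12245546 and 11121192 in sham, 12336479, 12135162, 10198699 and 11407706 in FLASH and 11122836, 11739769 and 11897146 in CONV. Between 22938 and 23988 genes were detected per skin library and between 17572 and 18604 per muscle library. The biological coefficient of variation was 0.428 in skin and 0.173 in muscle, so the same fold change was easier to detect in muscle.

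For 7 libraries the name of the deposited file belonged to another record of the same tissue, always among sham and FLASH libraries. Results are given by record, and beside them with files assigned by library name. With library names the coefficient of variation was 0.413 in skin and 0.159 in muscle. The comparisons of CONV with all other libraries are identical under both assignments and come first for each tissue.

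Skin after conventional-rate irradiation held higher levels of neutrophil, macrophage and matrix genes than sham and FLASH skin together, with camera calls that were lost (adjusted p = 0.265 with an estimated correlation). Cxcl2, a chemokine that attracts neutrophils, rose from 0.178 ± 0.405 CPM in the other 7 libraries to 35.7 ± 26.5 CPM (SD) in the 3 CONV libraries. Spp1, which encodes the matrix protein osteopontin, rose from 1.45 ± 1.82 to 99.5 ± 69.6 CPM. The fibrillar collagen genes Col1a1 and Col3a1 rose from 3811 ± 674 to 11379 ± 5821 CPM and from 2584 ± 591 to 9433 ± 4757 CPM. Ifnk, a type I interferon gene of keratinocytes, fell from 4.33 ± 1.29 to 1.29 ± 0.263 CPM.

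Of 20026 genes tested with edgeR, 317 were higher and 14 lower in CONV skin than in the other skin libraries. Among the 8 higher genes with the largest change, Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938, plus strand) changed by 7.57 ± 1.22 (log2 fold change ± SE, adjusted p = 0.0352). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) changed by 6.09 ± 0.88 and Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, minus strand), an inflammatory cytokine gene, by 5.08 ± 0.94. The others included Retnlg (ENSMUSG00000022651, 7.20 ± 1.17) and Acod1 (ENSMUSG00000022126, 6.91 ± 1.46), which makes itaconate in activated macrophages. They also included Ccl4 (ENSMUSG00000018930, 6.51 ± 1.07), the acute-phase gene Saa3 (ENSMUSG00000040026, 5.40 ± 0.95) and the myeloid receptor gene Trem1 (ENSMUSG00000042265, 5.07 ± 0.81), with adjusted p of 0.0352 to 0.0483. Ccl4 was uneven in CONV, at 0.458, 30.3 and 5.50 CPM in libraries 1 to 3, against 0.456 CPM in FLASH library 4. The 8 lower genes included Clca1 (ENSMUSG00000028255, -2.99 ± 0.63), H2-M5 (ENSMUSG00000024459, -2.39 ± 0.51), Gm45713 (ENSMUSG00000089989, -2.30 ± 0.49), Ifnk (ENSMUSG00000042993, chromosome 4, 35152056 to 35154005, plus strand, -1.74 ± 0.33) and Efcab1 (ENSMUSG00000068617, -1.31 ± 0.25). They also included Scg3 (ENSMUSG00000032181, -1.21 ± 0.22), the recombination repair gene Rad51b (ENSMUSG00000059060, -0.97 ± 0.18) and Vmn1r5 (ENSMUSG00000090346, -0.95 ± 0.18), with adjusted p of 0.0375 to 0.0487.

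All 20 tested neutrophil and acute inflammation genes were higher in CONV skin (median log2 change 4.57). Of these, 13 passed over all genes and 20 when adjusted over the list alone. Among them were Clec4e (3.92 ± 0.54) and Cxcl3 (4.51 ± 0.70). In the fibrillar collagen and matrix list, 29 of 31 genes were higher (median 1.79, of which at least 53.7% stayed without any 1 CONV library). Of these, 14 rose over all genes and 26 adjusted over the list alone, including Col5a1 (2.13 ± 0.32) and Col5a2 (2.27 ± 0.35). All 17 macrophage markers were higher (median 1.64, of which at least 65.9% stayed without any 1 CONV library). Of these, 7 rose, or 13 adjusted over the list alone, with Cd14 at 4.49 ± 0.65 and the complement gene C1qa at 1.91 ± 0.34. In the senescence-associated list 17 of 19 genes were higher (median 1.73), and 5 rose, or 13 adjusted over the list alone. Among its members, Plaur (3.65 ± 0.51) encodes a protease receptor and Mmp3 (3.97 ± 0.73) a matrix protease. All 14 wound and hyperproliferative keratinocyte genes were higher (median 2.91), of which the growth factor genes Hbegf (2.84 ± 0.49) and Areg (2.95 ± 0.63) passed under both adjustments and 12 did not. These 5 lists passed camera with its preset correlation, with adjusted p from 5.83e-21 to 5.84e-09. With an estimated correlation none did (adjusted p = 0.265 with an estimated correlation for the first 4 and 0.518 for the wound list), while fry gave 0.0167 to 0.0329.

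Smaller groups moved in part. Of 10 fibroblast markers, Fbln1 (1.15 ± 0.18) and Pdgfra (2.11 ± 0.41) rose, and 4 rose adjusted over the list alone. Of 14 endothelial markers, all higher (median 0.98), Tie1 rose (1.70 ± 0.32) and 9 rose adjusted over the list alone. Of 24 interferon-stimulated genes, 22 were higher (median 0.81), none passed over all genes and 9 passed adjusted over the list alone, with Bst2 at 1.22 ± 0.32. Both lists passed camera with the preset correlation only (adjusted p = 0.797 and 0.873 with an estimated correlation). The mast cell list had 1 of 9 genes past the threshold, the histamine-forming enzyme gene Hdc (3.96 ± 0.56), and its camera call was also lost (adjusted p = 0.873 with an estimated correlation). Of 14 immediate early genes Junb rose (1.53 ± 0.32). No p53 target passed under either adjustment (24 tested, 15 higher, median 0.25), and Cdkn1a, the p53-induced cell cycle inhibitor, was at 243 ± 94.2 CPM against 180 ± 34.5 (log2 0.43 ± 0.24, adjusted p = 0.296). Krt14, of basal keratinocytes, was at 8363 ± 8712 CPM against 1557 ± 1165 (2.42 ± 0.63, adjusted p = 0.0744). Adipoq, of fat cells, was at 11.6 ± 8.87 against 35.6 ± 34.5 CPM (-1.62 ± 0.96, adjusted p = 0.328), and all 12 adipocyte markers were lower with none past the threshold (median -1.06, adjusted p = 0.944 with an estimated correlation). Genes of other tissue in the samples varied beside these groups. The fast skeletal muscle list had a median of -1.73 with 0 of 15 genes called by edgeR, and the score of hair shaft genes ran from 4.43 to 8.37 in CONV and from -0.78 to 8.84 in the other libraries.

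The count of 331 genes was 0 without any single one of sham libraries 1, 2 and 3 or FLASH libraries 1, 2 and 3, and 1, 148, 1319 and 1454 without CONV library 3, CONV library 2, CONV library 1 and FLASH library 4. It was also 0 without the 2 libraries of disagreeing name, without the 2 muscle-rich libraries or with the hair shaft score as a covariate, and DESeq2 called 2078 genes, 1332 of them higher.

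**Figure D1:**
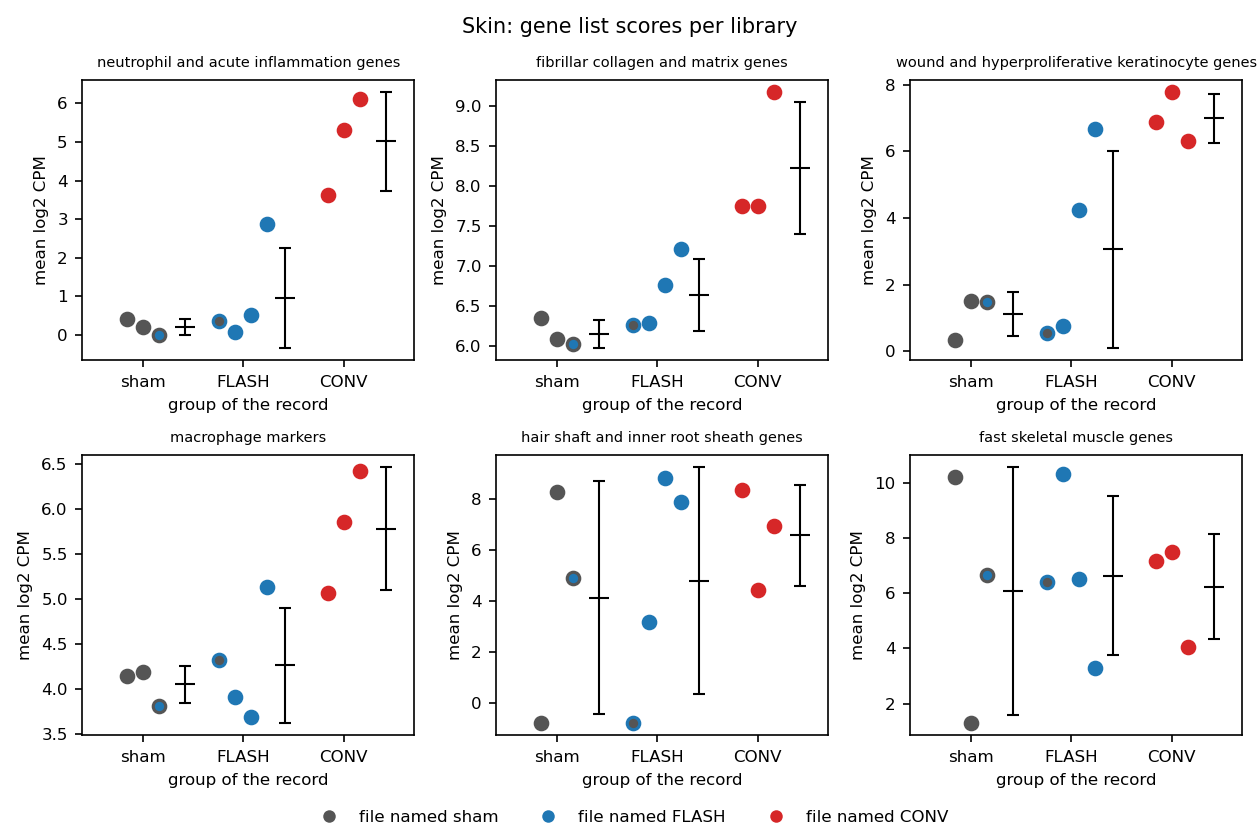
Mean log2 CPM of 6 gene lists per skin library (vertical axis) by group of the record (horizontal axis), with points filled by the group in the file name, outlined by the group of the record, and group mean ± SD at the right of each group. The 3 CONV libraries lie above all sham and FLASH libraries for the neutrophil list (3.62 to 6.11 against at most 2.87) and the matrix list, and FLASH library 4 lies near CONV for the wound list (6.66), while hair shaft and fast muscle scores spread within every group.

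Against sham alone no single gene passed in CONV skin, and the wound, neutrophil and matrix lists had higher medians (adjusted p = 0.438, 0.401 and 0.401 with an estimated correlation). The comparison asks what conventional-rate irradiation left in skin after 70 days. The wound list, made of keratinocyte genes of injured epidermis, had all 14 genes higher (median log2 6.21), and 13 passed adjusted over the list alone. Among them was the keratin gene Krt6a, at 3805 ± 1942 CPM against 82.6 ± 38.7. All 20 neutrophil genes were higher (median 5.87), 19 of them passing adjusted over the list alone. In the matrix list 29 of 31 matrix genes were higher (median 2.11), 25 passing in that way.

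edgeR called 0 of 20026 genes, with 4035 at an unadjusted p under the threshold, while DESeq2 called 1630. With files assigned by library name edgeR also called 0, with 5901 at an unadjusted p under the threshold. The 5 genes with the smallest p were Treml4, Slfn4, Plaur, Clec4e and Gng11, all with adjusted p = 0.127 (0.0669 by library name). Treml4 (ENSMUSG00000051682), a myeloid receptor gene, had no counts in sham and was at least 85.5-fold higher in CONV at the floor of 3 counts over the sham group. Slfn4 (ENSMUSG00000000204) was 4.70 ± 0.71, Plaur (ENSMUSG00000046223) 4.27 ± 0.66, Clec4e (ENSMUSG00000030142) 4.55 ± 0.72 and Gng11 (ENSMUSG00000032766) 2.19 ± 0.35 higher on the log2 scale. Col1a1 (1.76 ± 0.38) and Col3a1 (2.11 ± 0.40) had the same adjusted p. Krt14 was 3.00 ± 0.84 higher (adjusted p = 0.135), and Cdkn1a (0.50 ± 0.30) and Adipoq (-1.95 ± 1.11) had adjusted p of 0.365 and 0.345. Adjusted over the list alone, 12 of 17 macrophage markers (median 1.85), 7 of 14 endothelial markers (1.14) and 3 of 10 fibroblast markers passed, all higher. In the senescence-associated list 12 of 19 genes were higher and 1 lower in that way (2.35). Camera calls for the neutrophil, matrix, senescence, macrophage, wound and endothelial lists were lost (adjusted p = 0.401, 0.401, 0.401, 0.431, 0.438 and 0.755 with an estimated correlation). For these lists fry gave 0.0877 to 0.22. By library name, 6 of 12 adipocyte markers were lower adjusted over the list alone (median -1.83, adjusted p = 0.702 with an estimated correlation), with the leptin gene Lep at -4.04 ± 0.73, whereas none passed by record (median -1.35). In that assignment the 2 libraries with hair shaft scores of -0.78 both count as sham, and they had the highest Adipoq (96.1 and 70.7 CPM against 3.80 to 29.4 in the other 8). The call count rose from 0 to 406 without CONV library 1, to 89 without FLASH library 4 and to 1 without CONV library 3.

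Between FLASH and CONV skin no single gene passed over all genes, and the neutrophil and matrix lists had lower medians in FLASH (adjusted p = 0.288 with an estimated correlation for each). This is the comparison of the modalities at equal dose. All 20 neutrophil genes were lower in FLASH (median log2 -4.17), 19 of them adjusted over the list alone, with Trem1 at 1.42 ± 1.75 against 34.7 ± 24.5 CPM. Of 31 matrix genes 29 were lower (median -1.67), 23 of them adjusted over the list alone, with Spp1 at 2.02 ± 2.33 against 99.5 ± 69.6 CPM.

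edgeR called 0 of 20026 genes by record (2540 at an unadjusted p under the threshold, 457 called by DESeq2) and 0 by library name (2734). The smallest p belonged to Slfn4 (-3.82 ± 0.61), to Adam30 (ENSMUSG00000043468, -3.47 ± 0.56) and Cyp4f18 (ENSMUSG00000003484, -3.33 ± 0.54), which degrades the neutrophil attractant leukotriene B4. It also belonged to Treml4 (-4.67 ± 0.67) and the immediate early gene Csrnp1 (ENSMUSG00000032515, -1.86 ± 0.32), with an adjusted p of 0.249 each (0.221 by library name). Col1a1 (-1.46 ± 0.34) and Col3a1 (-1.71 ± 0.36) had the same adjusted p. Krt14 was at -2.11 ± 0.73 (0.319), Cdkn1a at -0.38 ± 0.28 (0.569) and Adipoq at 1.31 ± 1.04 (0.599). Adjusted over the list alone, 12 of 17 macrophage markers, 10 of 19 senescence-associated genes, 3 of 14 endothelial markers and 2 each of the wound (Hbegf, Areg), fibroblast and immediate early lists were lower in FLASH. The p53 list had 1 such gene, Btg2 (-0.97 ± 0.21). The camera calls of the neutrophil, matrix, macrophage and senescence lists were lost (adjusted p = 0.288 with an estimated correlation for each), and so was that of the wound list (0.454), with fry at 0.0789 to 0.151. The count was 117 without CONV library 1 and 1 without CONV library 3.

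No single gene passed between FLASH and sham skin, and the wound and neutrophil scores were high in 1 or 2 of the FLASH libraries. The comparison asks what FLASH irradiation left in skin after 70 days. All 14 wound genes were higher than in sham (median log2 4.16), with none passing under either adjustment. Krt16, a keratin of injured epidermis, was at 689 ± 1238 CPM against 12.0 ± 5.33. Dusp1, an immediate early phosphatase gene, was lower at 72.1 ± 23.4 against 191 ± 90.6 CPM, and passed adjusted over its list alone (adjusted p = 0.039).

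edgeR called 0 of 20026 genes by record (132 at an unadjusted p under the threshold, 4 called by DESeq2) and 0 by library name (1354). The genes with the smallest p were Gm8603 (ENSMUSG00000060417), with no counts in FLASH and at least 32.0-fold lower at the floor, Dusp1 (ENSMUSG00000024190, -1.41 ± 0.35) and Gm10108 (ENSMUSG00000062038), with 1 count in FLASH and 31 in sham (CPM ratio 0.0250, exact 95% counting interval 0.000614 to 0.150). Next were Spon2 (ENSMUSG00000037379, 0.81 ± 0.24) and Gm12070 (ENSMUSG00000069939), with no counts in sham and at least 11.6-fold higher, all with adjusted p of 1.00. Gm8603, Gm10108 and Gm12070 are pseudogenes and can share reads with their parent genes. Col1a1 (0.31 ± 0.35), Col3a1 (0.40 ± 0.36), Krt14 (0.89 ± 0.74), Cdkn1a (0.12 ± 0.28) and Adipoq (-0.64 ± 1.00) also had an adjusted p of 1.00. The wound list passed camera (adjusted p = 1.13e-10), which was lost (adjusted p = 0.408 with an estimated correlation), as were the calls of the neutrophil list (median 1.24, 0.515) and the matrix list (0.40, 0.486), and fry gave 0.956 for each. In FLASH, the wound score was 6.66 and 4.25 in libraries 4 and 3, and the neutrophil score 2.87 in library 4 against 0.0835 to 0.521 in the other 3. By library name, 5 of 12 adipocyte markers were lower adjusted over the list alone (median -1.33, adjusted p = 0.822 with an estimated correlation), with Lep at -3.10 ± 0.63. The 2 libraries of hair shaft score -0.78 both count as sham there and had the highest adipocyte scores (6.97 and 6.52), and all 22 hair shaft genes were higher with none passing (median 0.84, adjusted p = 0.88 with an estimated correlation). In that assignment all 14 wound genes were higher, and Krt6b, Stfa3 and Stfa1 passed adjusted over the list alone (median 4.39, adjusted p = 0.88 with an estimated correlation).

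**Figure D2:**
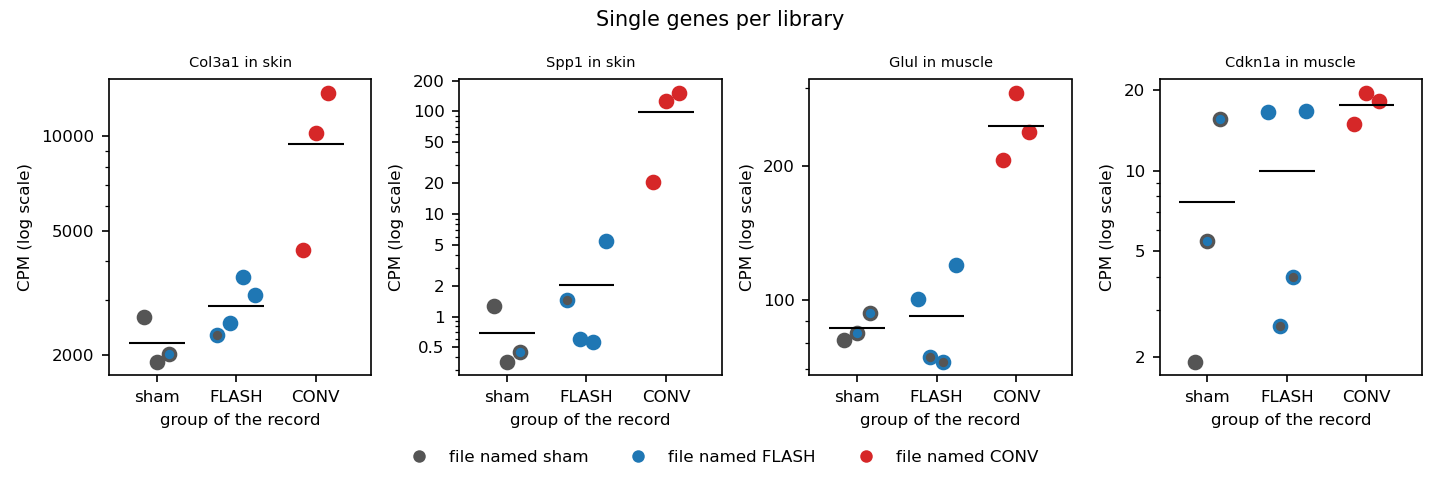
Expression (CPM, log scale, vertical axis) of Col3a1 and Spp1 in skin and of Glul and Cdkn1a in muscle per library by group of the record (horizontal axis), with points filled by the group in the file name, outlined by the group of the record, and a line at the group mean. Glul lies above all sham and FLASH libraries in the 3 CONV muscle libraries (246 ± 43.2 CPM against 89.7 ± 16.7), and Cdkn1a in muscle is low in the 3 libraries whose file is named sham (2.84 ± 1.06 CPM).

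In muscle after conventional-rate irradiation edgeR called 8 genes against the other muscle, led by Glul. Of 100 splits of the libraries, 3 gave as many genes, the real one included. Glul, the glutamine synthetase gene, rose from 89.7 ± 16.7 CPM in the other 7 libraries to 246 ± 43.2 CPM in the 3 CONV libraries. Adora1, an adenosine receptor gene, rose from 1.20 ± 0.619 to 5.23 ± 0.729 CPM, and Mettl11b, an N-terminal methyltransferase gene, fell from 11.6 ± 1.46 to 5.81 ± 0.788 CPM. All 11 denervation-responsive genes were higher (median log2 0.72, adjusted p = 0.0581 with an estimated correlation), 4 of them adjusted over the list alone, among them Chrna1, the acetylcholine receptor subunit gene, at 7.61 ± 1.47 against 4.00 ± 1.27 CPM.

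Of 13080 genes tested with edgeR, 6 were higher and 2 lower, and DESeq2 called 150. Glul (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723, plus strand) changed by 1.45 ± 0.14 (adjusted p = 0.000945). Adora1 (ENSMUSG00000042429, chromosome 1, 134199223 to 134235431, minus strand) changed by 2.11 ± 0.34, Fam126b (ENSMUSG00000038174) by 0.80 ± 0.14, and Nrip1 (ENSMUSG00000048490), a nuclear receptor corepressor, by 0.71 ± 0.12 (adjusted p = 0.0475 each). Pcnt (ENSMUSG00000001151), a centrosome gene, changed by 0.54 ± 0.09 and Adgrl1 (ENSMUSG00000013033) by -0.73 ± 0.12, each with adjusted p = 0.0475. Mettl11b (ENSMUSG00000040113) changed by -0.99 ± 0.14 (adjusted p = 0.0198), and the remaining higher gene, Frem2, lies outside the rule and was named after its values were seen. Col1a1 (-0.64 ± 0.54, adjusted p = 0.688) and Col3a1 (-0.76 ± 0.31, 0.388) did not pass. Nor did Cdkn1a (0.96 ± 0.65, 0.603), Myh4 (-0.21 ± 0.17, 0.661) or Myh7 (2.99 ± 1.57, 0.49).

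Adjusted over the list alone, 4 of 11 denervation genes rose, Chrna1 (0.92 ± 0.22), Sln (5.08 ± 1.09), Ankrd1 (2.09 ± 0.55) and Chrnd (1.26 ± 0.45), and 0 passed edgeR over all genes. Levels in CONV were uneven for Sln (11.9 ± 16.8 against 0.332 ± 0.332 CPM) and Ankrd1 (11.5 ± 8.71 against 2.74 ± 1.47 CPM). The camera call of this list was lost (adjusted p = 0.0581 with an estimated correlation), and fry gave 0.0332. All 12 slow muscle genes were higher (median 2.69) with none passing under either adjustment (adjusted p = 0.484 with an estimated correlation), and their score was 2.18, 7.69 and 6.41 in CONV libraries 1 to 3 against 1.18 to 5.6 in the others. Of 14 immediate early and heat shock genes 5 rose adjusted over the list alone (median 0.42, adjusted p = 0.408 with an estimated correlation), with Hspa1b at 12.4 ± 10.3 against 1.92 ± 0.705 CPM and Hspa1a at 18.1 ± 15.6 against 3.67 ± 2.05. In the satellite cell and regeneration list, Myod1 (0.77 ± 0.17), the neonatal myosin gene Myh8 (0.81 ± 0.22) and the embryonic myosin gene Myh3 (3.18 ± 0.80, at 13.4 ± 14.5 against 1.45 ± 0.816 CPM) rose and Heyl (-0.51 ± 0.17) fell, adjusted over the list alone (9 tested, median 0.16). Of 16 clock genes, Per2 rose (1.04 ± 0.20) and Nr1d1 (-1.33 ± 0.24) and Clock (-0.34 ± 0.11) fell in that way. Of 28 matrix genes 20 were lower (median -0.35), Loxl2 (-0.93 ± 0.23), Col5a1 (-0.57 ± 0.15) and Col6a1 (-0.59 ± 0.16) fell and Col8a1 rose (0.70 ± 0.20), adjusted over the list alone (adjusted p = 0.643 with an estimated correlation). The glycolysis genes Pfkm (-0.47 ± 0.11), Gapdh (-0.37 ± 0.12) and Eno3 (-0.37 ± 0.12) fell likewise (14 tested, median -0.20, adjusted p = 0.491 with an estimated correlation), and all 18 fatty acid oxidation genes were higher with none passing (median 0.25, adjusted p = 0.625 with an estimated correlation). No p53 target passed (20 of 23 higher, median 0.23, adjusted p = 0.484 with an estimated correlation).

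The count of 8 genes was 89 without CONV library 1, 31 without FLASH library 1 and 1 to 3 without any other library. It was 0 without the 5 libraries of disagreeing name, which left 1 sham, 1 FLASH and 3 CONV libraries, 1 with counts rebuilt from TPM, 2 with the slow muscle score as a covariate and 53 (24 higher) with no low-count filter.

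**Figure D3:**
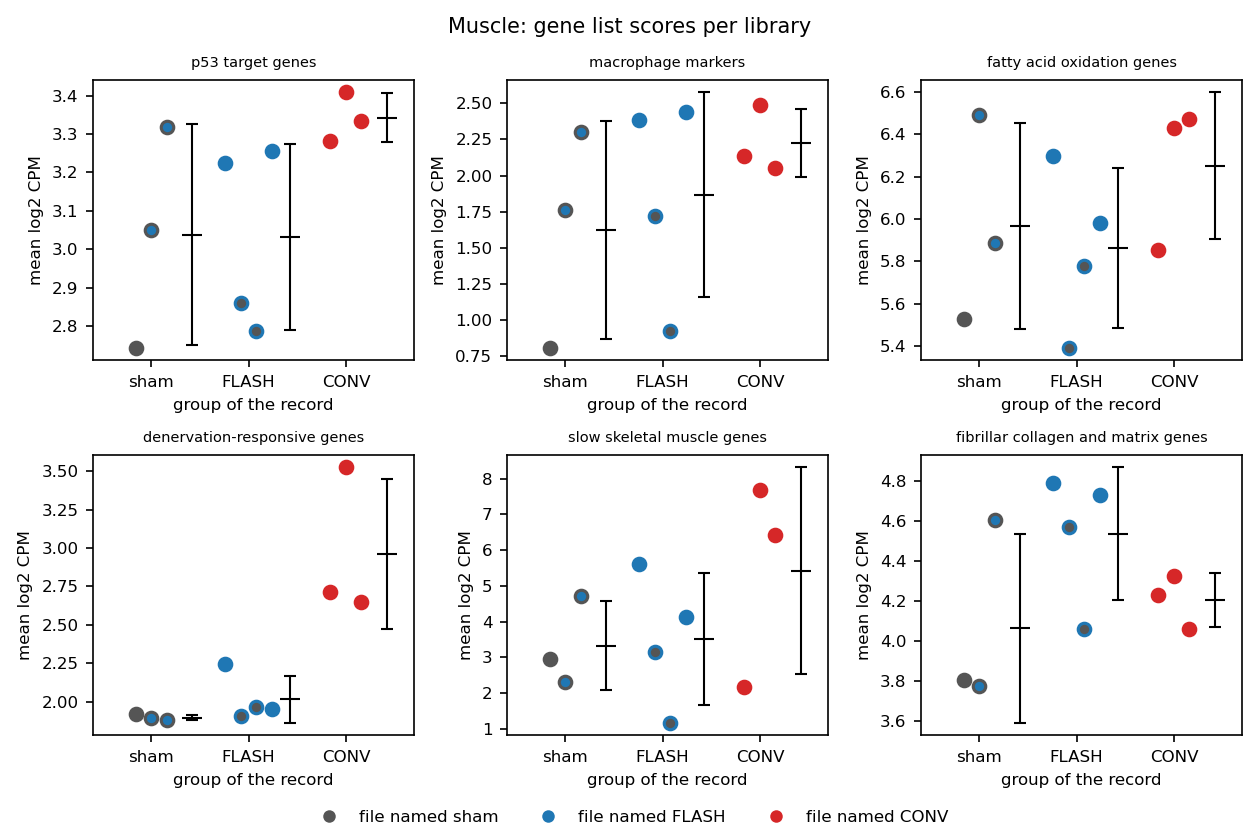
Mean log2 CPM of 6 gene lists per muscle library (vertical axis) by group of the record (horizontal axis), with points filled by the group in the file name, outlined by the group of the record, and group mean ± SD at the right of each group. Denervation genes lie highest in the 3 CONV libraries (2.65 to 3.52 against 1.88 to 2.24), and p53 targets lie lowest in the 3 libraries whose file is named sham (2.75 to 2.86 against 3.05 to 3.41).

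Against sham alone, the muscle result of CONV depended on which files counted as sham. By record Glul was the only gene called, at 246 ± 43.2 CPM in CONV against 86.6 ± 6.38 in sham (log2 1.5 ± 0.19, adjusted p = 0.0338). By library name 67 genes rose and 97 fell, among them Cdkn1a, which rose from 2.84 ± 1.06 to 17.6 ± 2.39 CPM (2.64 ± 0.45, adjusted p = 0.0389), whereas by record it was at 7.65 ± 7.11 in sham (1.20 ± 0.85, adjusted p = 0.689). Adjusted over the list alone, 9 of 15 macrophage markers and 7 of 18 fatty acid oxidation genes were also higher by library name, and 9 of 15 fast muscle genes lower and 1 higher (adjusted p = 0.245 with an estimated correlation for each list).

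By record, edgeR called 1 of 13080 genes (1312 at an unadjusted p under the threshold, 49 called by DESeq2). The other genes with the smallest p were Adora1 (2.72 ± 0.41, adjusted p = 0.0754), Mettl11b (-1.0 ± 0.16, 0.127), Fhl3 (ENSMUSG00000032643, -0.68 ± 0.12, 0.199) and Adgrl1 (-0.75 ± 0.14, 0.199). Col1a1 (-0.03 ± 0.54), Col3a1 (-0.72 ± 0.38), Myh4 (-0.26 ± 0.21) and Myh7 (3.46 ± 2.29) had adjusted p of 0.569 to 0.991. All 11 denervation genes were higher (median 0.76), 4 of them adjusted over the list alone, with Myog at 1.5 ± 0.47 (adjusted p = 0.0905 with an estimated correlation, fry 0.0478). The 1 call was lost without any of sham libraries 2 and 3, FLASH library 1 and CONV libraries 2 and 3, became 2 without FLASH library 2 and 29 without CONV library 1. It was 23 with no low-count filter. Without the 5 libraries of disagreeing name, which left 1 sham and 1 FLASH library, Glul was at 1.58, and the CONV libraries alone gave the spread.

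By library name, the 8 higher genes of largest change included Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand), Ift81 (ENSMUSG00000029469, 2.18 ± 0.40), Adora1 (2.01 ± 0.44), the matrix gene Postn (ENSMUSG00000027750, 1.98 ± 0.38) and the lipid droplet gene Plin5 (ENSMUSG00000011305, 1.82 ± 0.31). They also included the mitochondrial carrier gene Ucp2 (ENSMUSG00000033685, 1.73 ± 0.26), Glul (1.69 ± 0.14, adjusted p = 0.000106) and Depp1 (ENSMUSG00000048489, 1.62 ± 0.32). The 8 lower genes included Wnk3 (ENSMUSG00000041245, -1.57 ± 0.25), the clock gene Nr1d1 (ENSMUSG00000020889, -1.46 ± 0.27), Atp13a5 (ENSMUSG00000048939, -1.44 ± 0.25) and the mitotic kinase gene Aurka (ENSMUSG00000027496, -1.41 ± 0.32). They also included Nrep (ENSMUSG00000042834, -1.32 ± 0.21), Ccrl2 (ENSMUSG00000043953, -1.29 ± 0.29), Pld5 (ENSMUSG00000055214, -1.25 ± 0.25) and Auts2 (ENSMUSG00000029673, -1.08 ± 0.16). Of 23 p53 targets 21 were higher (median 0.37), with Cdkn1a and Trp53inp1 (0.70 ± 0.13) past the threshold over all genes and 10 adjusted over the list alone (adjusted p = 0.0898 with an estimated correlation, fry 0.00707). All 15 macrophage markers were higher (median 0.98), Cd68 (1.82 ± 0.34) and C1qc (1.47 ± 0.29) over all genes and 9 adjusted over the list alone. Of 18 fatty acid oxidation genes, all higher (median 0.52), 7 passed adjusted over the list alone, with Pdk4 at 1.68 ± 0.35. The slow muscle list had 7 of 12 genes higher in that way (median 4.24). The fast muscle list had 9 lower and 1 higher of 15 (median -0.39), with Casq1 at -0.68 ± 0.14, and the glycolysis list had 5 lower of 14 (median -0.33). The camera calls of these 5 lists were lost (adjusted p = 0.245 with an estimated correlation for each).

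Between FLASH and CONV muscle, Glul was the only gene that passed over all genes under both assignments. Glul was at 92.0 ± 22.7 CPM in FLASH against 246 ± 43.2 in CONV (-1.42 ± 0.17, adjusted p = 0.024; -1.30 ± 0.13 by library name, adjusted p = 0.00087). Denervation genes were all lower in FLASH (11 tested, median -0.59, adjusted p = 0.127 with an estimated correlation), and Chrna1 (-1.06 ± 0.26) and Sln (-5.33 ± 1.44, uneven in CONV at 11.9 ± 16.8 CPM) passed adjusted over the list alone. Also lower were all 12 slow muscle genes (median -2.63) and all 6 red blood cell genes (-1.52, or 0.376 without CONV library 3), with none passing, and 13 of 14 immediate early and heat shock genes (-0.52), with Hspa1b (-2.56 ± 0.56) passing in that way (adjusted p = 0.471, 0.544 and 0.318 with an estimated correlation). Of 28 genes of the matrix list, the collagen genes Col6a1 (0.71 ± 0.15) and Col5a1 (0.64 ± 0.16) and the lysyl oxidase-like gene Loxl2 (1.04 ± 0.24) were higher in FLASH adjusted over the list alone (adjusted p = 0.471 with an estimated correlation).

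edgeR called 1 of 13080 genes by record (1086 at an unadjusted p under the threshold, 41 called by DESeq2) and 1 by library name (1114). The next genes were Fat4 (ENSMUSG00000046743, 0.65 ± 0.10, adjusted p = 0.0877), Mettl11b (0.99 ± 0.16, 0.0877), Tnk2 (ENSMUSG00000022791, 0.81 ± 0.14, 0.147) and Adgrl1 (0.71 ± 0.13, 0.206). Cdkn1a was at 9.99 ± 7.74 CPM in FLASH and 17.6 ± 2.39 in CONV (-0.80 ± 0.77, adjusted p = 0.811), and Col1a1, Col3a1, Myh4 and Myh7 had adjusted p of 0.60 to 0.847. The camera calls of the 5 lists above (matrix median 0.46) were all lost with an estimated correlation. By library name, 8 of 13 mitochondrially encoded genes were higher in FLASH adjusted over the list alone (median 0.43, adjusted p = 0.525 with an estimated correlation). The 1 call was lost without any of sham libraries 1 to 3, FLASH libraries 2 and 3 and CONV libraries 2 and 3. The count was 5 without FLASH library 1, 24 without CONV library 1, 0 with only the 2 groups in the fit and 21 with no low-count filter. Without the libraries of disagreeing name 1 FLASH and 1 sham library were left, so no count is given.

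No single gene passed between FLASH and sham muscle, and every list call was lost with an estimated correlation under both assignments. By record, 27 of 28 matrix genes were higher in FLASH (median log2 0.26, adjusted p = 0.795 with an estimated correlation) with none passing, and Cdkn1a was at 9.99 ± 7.74 against 7.65 ± 7.11 CPM (0.39 ± 0.83, adjusted p = 0.999). By library name, 10 of 15 macrophage markers were higher adjusted over the list alone, with C1qc at 6.13 ± 0.987 against 2.27 ± 1.14 CPM, and so were 8 of 16 antigen presentation genes, with H2-Eb1 at 11.2 ± 3.17 against 4.52 ± 1.15 CPM (adjusted p = 0.116 and 0.143 with an estimated correlation). In that assignment 7 of 23 p53 targets were higher adjusted over the list alone, with Cdkn1a at 13.6 ± 5.47 against 2.84 ± 1.06 CPM (2.27 ± 0.44, adjusted p = 0.219 over all genes; adjusted p = 0.0931 with an estimated correlation for the list).

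edgeR called 0 of 13080 genes by record (327 at an unadjusted p under the threshold, 1 called by DESeq2) and 0 by library name (1293). By record the genes with the smallest p were Arhgap23 (ENSMUSG00000049807, 0.58 ± 0.12), the pseudogene Rpl10a-ps1 (ENSMUSG00000084416, -3.74 ± 0.73) and Cercam (ENSMUSG00000039787, 1.56 ± 0.34). Next were the elastic fibre gene Mfap4 (ENSMUSG00000042436, 1.40 ± 0.31) and Ctnnd2 (ENSMUSG00000022240, 0.85 ± 0.20), all with adjusted p = 0.999. Col1a1 (0.94 ± 0.52), Col3a1 (0.07 ± 0.35), Myh4 (-0.08 ± 0.20) and Myh7 (0.75 ± 1.99) had the same adjusted p. The matrix list passed camera with the preset correlation (adjusted p = 1.9e-12; adjusted p = 0.795 with an estimated correlation). By library name they were Ttyh2 (ENSMUSG00000034714, -0.98 ± 0.15) and the clock repressor gene Bhlhe41 (ENSMUSG00000030256, -0.74 ± 0.12), both with adjusted p = 0.0809. Next were Myadm (ENSMUSG00000068566, 0.80 ± 0.14), Mafa (ENSMUSG00000047591, -0.77 ± 0.14) and Depp1 (1.63 ± 0.30), with adjusted p = 0.179. By library name the medians were 0.94 for macrophage markers, 0.64 for antigen presentation and 0.32 for p53 targets (adjusted p = 0.116, 0.143 and 0.0931 with an estimated correlation), and fry gave 0.0789, 0.0789 and 0.0287.

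By record edgeR called 3 genes whose difference between FLASH and CONV was not the same in the tissues, and by library name it called 154 for the CONV response, a test that recovered 2% of simulated 2-fold differences. In the CONV response by record, the collagen genes Col5a1 and Col5a2 and the matrix gene Fbln2 had the smallest p together with Rpl14-ps1 and Clca3a1. Col5a1 was at 895 ± 551 CPM in CONV and 190 ± 27.6 in sham skin, and at 22.7 ± 2.85 and 29.3 ± 6.57 in muscle. The difference of the log2 changes, muscle minus skin, was -2.85 ± 0.47 for Col5a1, -2.79 ± 0.53 for Col5a2 and -2.87 ± 0.54 for Fbln2, each with adjusted p = 0.141 by record and 0.0272, 0.0422 and 0.0381 by library name.

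Of 19199 genes, edgeR called 0 for the FLASH response (371 at an unadjusted p under the threshold, 6 by DESeq2), 0 for the CONV response (2737, and 263 by DESeq2) and 3 for FLASH against CONV (99 by DESeq2). By library name these were 0 (1369 at an unadjusted p under the threshold), 154 (52 higher in muscle) and 1. The 3 genes were Twist1 (ENSMUSG00000035799), a mesenchymal transcription factor gene, and the near-identical receptor genes Gm10662 and Gm5891, which share reads. Twist1 had 38 counts in FLASH and 3 in CONV muscle (CPM ratio 9.55, exact 95% counting interval 3.03 to 48.3) and 11.9 ± 3.10 against 17.7 ± 6.11 CPM in skin (adjusted p = 0.0398 for the difference, 0.00995 by library name). The CONV count was 161 without skin CONV library 1, 16 without skin FLASH library 4 and 1 without muscle FLASH library 2, which also gave 1 for the FLASH response, and that of FLASH against CONV was 78 and 22 without the first 2 of these and 0 without skin FLASH library 2, skin CONV library 3, muscle FLASH libraries 1, 2 and 4 or muscle CONV library 3.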

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

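The tests of the 3 patterns weighed here and the splits of the libraries were chosen after the results were seen, and for the slow muscle score and the clock genes the deciding values were set before those 2 tests were run.

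Inflammation, matrix, macrophage and wound genes were higher in CONV skin than in sham and FLASH skin (median log2 changes 4.57, 1.79, 1.64 and 2.91), with adjusted p = 0.265 for the first 3 and 0.518 for the wound list with an estimated correlation. With the fast muscle score as a covariate, the count of called genes stayed within 1.5 times the main count of 331. Without the 2 muscle-rich libraries it went to 0. With the fast muscle covariate the 4 lists kept at least 93.0% of their median change, which argues against skeletal muscle RNA in some skin libraries as the whole cause. With the hair shaft score they kept at least 96.2%, which argues against the hair cycle as the whole cause, although the count again went to 0 as the smallest adjusted p rose from 0.0352 to 0.0579, with the neutrophil median at 4.52 (quartiles 3.67 to 5.35) against 4.57 (3.55 to 5.33). Without any single CONV library they kept at least 53.7%, lowest in the matrix list, which argues against 1 library as the whole cause. The count nevertheless fell to 1 without CONV library 3 and to 148 without CONV library 2. It was 1319 without CONV library 1, 1454 without FLASH library 4 and 0 without any of sham libraries 1 to 3 and FLASH libraries 1 to 3. A late response of skin that is larger after conventional-rate irradiation and a skin wound at sampling both stay open and were not tested here.

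The muscle results changed with the assignment of the files to records. Of the 35 ways to choose 3 sham libraries among the 7 sham and FLASH libraries, the assignment by library name ranked 1 by genes called for CONV against sham (164, against 77 for the next and 1 for the record). In skin the assignment by library name called 0 (5901 at an unadjusted p under the threshold, 4035 by record, where DESeq2 called 1630) and that with FLASH 1, FLASH 2 and sham 1 as sham called 4375, so such counts also follow other structure and the rank does not settle an exchange of files. Over 16 clock genes the mean correlation of skin with muscle was 0.130 when paired by library name and 0.00125 when paired by record (exact one-sided p = 0.217 and 0.496 over 5040 pairings of 7 animals), so this test did not decide, and it assumes that 1 animal gave both tissues. Seen after the results, muscle Cdkn1a (1.91 to 3.99 CPM in the 3 files named sham against 5.43 to 16.8 in the 4 named FLASH) and the p53 score (2.75 to 2.86 against 3.05 to 3.32) also parted by library name, and an exchange of files and a difference between animals that follows the names both stay open.

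Denervation-responsive genes were higher in CONV muscle (median log2 change 0.72, quartiles 0.32 to 1.09). With the slow muscle score as a covariate the median was 0.58 (quartiles 0.24 to 0.98), which argues against a larger share of slow fibres as the whole cause. Without any single CONV library it was at least 0.60, which argues against 1 library as the whole cause. The cause stays open, and the adjusted p of 0.0581 with an estimated correlation did not pass.

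Other splits of the same libraries were fitted for each count of genes called by edgeR. For CONV against all other libraries in skin 1 of 100 splits, the real one, had as many genes (331, highest other 19). That is the smallest share that 100 splits can give, and no adjustment was made for the 11 comparisons. It argues against chance for this count but does not exclude it. For FLASH against CONV between the tissues 1 of 30 splits had as many genes by record (3, highest other 1), the smallest share that 30 splits can give. The share was under 0.05, but 2 of the 3 genes share reads and have the same values, so it does not exclude chance. None of the 3 genes passed the low-count filter in muscle alone. By library name, where no splits were fitted, the count was 1. For CONV against all other libraries in muscle 3 of 100 splits did (8, highest other 89), a share of 0.03. That share was under 0.05, but 2 other splits of the same libraries gave as many genes, so the count alone does not exclude chance. Chance cannot be excluded for FLASH against CONV in muscle (1, 5 of 35, highest other 31). With 0 genes every split has as many, so the splits say nothing for FLASH against sham in skin (0 genes, 35 of 35 splits, highest other 1437), FLASH against CONV in skin (0, 35 of 35, highest other 0), FLASH against sham in muscle (0, 35 of 35, highest other 19), or the FLASH and CONV responses between tissues (0 and 0, 30 of 30 each, highest other 1 and 0). At an unadjusted p under the threshold edgeR had 132, 2540, 327, 371 and 2737 genes in these 5, where DESeq2 called 4, 457, 1, 6 and 263. For CONV against sham the 10 splits are too few for a share under 0.05, with 0 genes in skin (10 splits with as many, highest other 1; 4035 at an unadjusted p under the threshold, 1630 by DESeq2) and 1 in muscle (3 splits, highest other 1). The split with 1437 genes sets sham library 1 and FLASH libraries 1 and 2 of skin apart, and the one with 31 also exceeds the real count several times, so both point to a structure of the libraries. Those skin libraries also had the lowest hair shaft scores.

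Library measures were screened in groups of 4, and 8 of 83 groups held a library far from the rest, where chance flags about 1 in 20 groups. In skin FLASH library 4 the neutrophil score was 2.87 against 0.0835 to 0.521 in the other 3 (gap over range 0.843). In skin FLASH library 2 the score of mitochondrially encoded genes was 11 against 9.48 to 9.66 (0.883), the satellite cell score 3.93 against 1.57 to 1.93 (0.847), the mitochondrial share 4.52% against 1.79% to 1.87% (0.971) and the share of the 10 most abundant genes 12.9% against 4.54% to 5.31% (0.908). Skin sham library 1, in a group that was not screened, had shares of 5.09% and 12.9%. Both are the skin libraries rich in muscle RNA. In muscle FLASH library 3 the adipocyte score was 2.36 against 3.46 to 3.66 (0.840) and the basal keratinocyte score 3.58 against 3.77 to 3.79 (0.907). The screen used groups by record, in which muscle FLASH libraries 2 and 3 hold files named as sham libraries. In muscle FLASH library 1 the denervation score was 2.24 against 1.91 to 1.96 (0.837).

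By the test of the difference between muscle and skin in the response of FLASH against CONV, 3 genes stood out. Twist1 differed by 4.03 ± 0.63 (adjusted p = 0.0398), and by 4.23 (0.00995) with files assigned by library name. Gm10662 and Gm5891, with the same values and shared reads, differed by -9.38 ± 1.23 (adjusted p = 0.0188), and by -2.31 (0.436) by library name, with 0 counts in FLASH and 24 in CONV muscle (at least 10.6-fold lower) against 406 and 173 counts in skin. The count of 3 was 78 without skin CONV library 1, 22 without skin FLASH library 4 and 0 without skin FLASH library 2, skin CONV library 3, muscle FLASH libraries 1, 2 and 4 or muscle CONV library 3.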

How the results depend on the processing

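The list medians without each replicate, the covariates and the removal of muscle-rich skin libraries were chosen after the results were seen. Named genes kept their side of the threshold in 1537 values, lost the call in 289 and gained it in 68. The 1537 values do not show that direction was kept, as a gene without a call could change sign and still count. Lists kept their direction and side of the threshold in 1566 values and lost the call in 263. Counts of called genes stayed within 1.5 times the main count in 161 cases and moved in 87. All 90 list calls of camera were lost with an estimated correlation. Simulated 2-fold changes, in genes with an average log2 CPM above 1, were recovered for 73% to 86% of genes in muscle and 5% to 19% in skin, although skin had the greater depth. The cause was not tested for the changes below unless stated.

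DESeq2 called 4, 1630, 457 and 2078 genes in skin and 1, 49, 41 and 150 in muscle for FLASH against sham, CONV against sham, FLASH against CONV and CONV against all others, and 6, 263 and 99 between tissues. With no low-count filter the last 3 muscle counts were 23, 21 and 53. With only the compared groups fitted, muscle CONV against sham gave 2 and FLASH against CONV 0. By library name, CONV against sham gave 164 in muscle and 154 between tissues, and FLASH against CONV between tissues 1. Without the libraries of disagreeing name, edgeR called 0 for CONV against all others in both tissues. This leaves 1 sham and 1 FLASH library in muscle, so counts for comparisons that set either of them alone as a group are not given. CONV against all others gave 1 in muscle with counts rebuilt from TPM (100% higher), 0 in skin without the muscle-rich libraries or with the hair shaft score, and 2 in muscle with the slow muscle score (50% higher). With no filter 45.3% were higher, and with DESeq2 43.3% in muscle and 64.1% in skin.

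Leaving out each replicate gave ranges of 0 to 0, 0 to 406, 0 to 117 and 0 to 1454 genes in skin, 0 to 0, 0 to 29, 0 to 24 and 1 to 89 in muscle, in the order above, and 0 to 1, 0 to 161 and 0 to 78 between tissues. The highest counts were without CONV library 1 of the tissue (of skin for the 161 and 78), except 1454 without skin FLASH library 4 and 1 without muscle FLASH library 2.

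With the replicate block, counts were 15 for CONV against sham, 1 for FLASH against CONV and 1292 for CONV against all others in skin, 0, 0 and 1 in muscle, and 0 for FLASH against CONV between tissues. Replicate number 4 occurs only in FLASH, so within a tissue the block in effect removes FLASH library 4 from the comparison. Between tissues the block joined the skin and muscle libraries of the same group and replicate number. Same-numbered libraries correlated at -0.711 to 0.517 in skin (3 of 9 pairs over 0.1), -0.235 to 0.213 in muscle (1 of 9) and -0.0460 to 0.0736 across tissues (0 of 10). In each tissue 1 of 10 libraries correlated best with its own number. These correlations gave no sign that record numbers pair the libraries. A pairing is not excluded, as some files carry the library name of another record.

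The median of a called list turned sign in 12 cases. For FLASH against sham in skin these were macrophage (-0.0016) and mast cell (-0.146) with the replicate block, and B cell (-0.0927) and endothelial (-0.120) by library name. Over the left-out replicates the mast cell median was -0.121 (without FLASH replicate 4) to 0.849 and the slow muscle median -0.246 (without FLASH replicate 2) to 1.53. In muscle, immediate early genes turned by library name (0.388, FLASH against sham). Fatty acid oxidation ranged from -0.0094 (without sham replicate 1) to 0.476 for CONV against sham. Red blood cell genes ranged from -2.4 (without muscle FLASH replicate 4) to 0.376 for FLASH against CONV in muscle and from -0.146 to 2.37 for CONV against all others, turning without CONV replicate 3. Slow muscle genes turned, by construction, with their own score as covariate (0.0907 for FLASH against CONV and -0.0292 for CONV against all others).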

Other observations

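The list median without a CONV library and the values per library were chosen after the results were seen, and the other tests in this part were planned.

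Hair shaft and inner root sheath genes, which mark growing hair follicles, parted the skin libraries. Their score was -0.78 in sham library 1, -0.78 in FLASH library 1 and 3.18 in FLASH library 2, and 4.43 to 8.84 in the other 7, among them all CONV libraries. The hair shaft list was not called in any skin comparison by record (median log2 change 0.66 for FLASH against sham and 0.10 for CONV against all others), and by library name, where both libraries at -0.78 count as sham, its camera call for FLASH against sham (22 of 22 genes higher, median 0.84) was lost (adjusted p = 0.88 with an estimated correlation). Fast skeletal muscle genes had scores of 10.2 in sham library 1 and 10.3 in FLASH library 2 of skin, and 1.30 to 7.50 in the other 8. The slow muscle list had a median of -0.63 in CONV against all other skin, with 0 of 12 genes called by edgeR.

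Clock genes were lower in CONV skin as a list (14 of 16 lower than in the other libraries, median -0.64), with none passing under either adjustment (adjusted p = 0.873 with an estimated correlation). In muscle, Nr1d1, a clock repressor, was lower in CONV than in sham (-1.41) and Per2 higher (1.00), both adjusted over the list alone. Metallothionein genes of the atrophy list rose in CONV muscle against all others, adjusted over the list alone (Mt1 1.79, Mt2 2.32), while the list went both ways (3 higher and 2 lower of 15, median 0.03). The fat droplet gene Plin4 rose in the same comparison (1.08), as 1 of 12 adipocyte markers (median 0.49, adjusted p = 0.408 with an estimated correlation). The red blood cell list had a median of 1.84 with none of 6 genes passing (adjusted p = 0.491 with an estimated correlation), and CONV library 3 set its direction, as the median was -0.146 without it.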
